A study of Mus musculus with 6 samples.

How the data were processed

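Cytoplasmic RNA of naive CD8 T cells was compared between male mice heterozygous for the C587R change in NXF1 and wild-type littermates, on the BALB/c background, with 3 mice of each genotype. Per the labels' protocols, CD8-positive spleen cells were enriched magnetically and then sorted by flow cytometry as CD8-positive cells with low CD44 and with CD62L. RNA of these cells was separated into a cytoplasmic and a nuclear fraction with a Norgen kit, and only the cytoplasmic fraction was sequenced. Libraries were made from polyadenylated RNA with the Illumina TruSeq RNA v2 kit, which does not mark the strand of a transcript. A residue of nuclear RNA in the fraction, or a change in the total RNA of a cell, cannot be read from such libraries, because the values are shares of the RNA recovered.

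The deposited values are whole read counts per gene with an exonic length per gene. Per the submitters' processing notes, the authors used CASAVA 1.8.2, Subread 1.2.2 and featureCounts 1.3.5-p5 with genome build mm10, which is assembly GRCm38. The annotation release, the strand setting and any filter on reads are not given in the sources used here. Without a strand setting, reads from overlapping genes on opposite strands cannot be told apart, and reads of near-identical paralogs could be split or lost. Total counts per library ranged from 17596704 to 20367206. Every row named a gene, and the tables held 27152 genes. Rn45s, the ribosomal RNA precursor, took 2.32% to 3.94% of the counts, more in the mutant library of each batch, and stayed in the tables.

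Samples were grouped by the genotype in the labels. In batch 1 the animal number in the title and the number in the description are crossed between the mutant mouse (176 and 174) and the wild-type mouse (174 and 176), while they match in the other 4 samples. The genotype label was kept, and results were recomputed with the genotypes of batch 1 exchanged and without batch 1. Each library is from a different mouse per the labels and counted as 1 sample. Pairs of libraries within a group had a chi-square per gene from 4.35 to 16.4, so none was taken for 1 library deposited again. The labels state that mice are littermates and give each mouse a batch, with 1 mutant and 1 wild type in each of the 3 batches, and this is where the pairing comes from. Deviations from the group means correlated with r = 0.317, 0.000582 and 0.392 between the libraries of batches 1, 2 and 3, and the second principal component (25.0% of the variance) ordered the libraries by batch.

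Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept with filterByExpr, which left 12570 genes holding 99.9% of the counts. Library sizes were scaled by TMM, and genotype was tested with glmQLFit (robust) and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The main fit had no block, and the fit with batch as the replicate block was its alternative. CPM values are counts relative to the TMM-scaled library size, and log2 fold changes are mutant minus wild type as edgeR fitted them. The standard error of a log2 fold change was taken from the spread of log2 CPM (prior count of 2) among the 3 mice of each genotype. Within-batch values are differences of these log2 CPM between the 2 libraries of a batch.

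A total of 27 gene lists fitting naive CD8 T cells, mRNA export and other cell types of the spleen were written before the data were examined, as were the tests, the alternatives and the rule for named genes. The lists were mRNA export, nuclear pore, SR and SR-like splicing factors, nonsense-mediated decay, snoRNA hosts, nuclear-enriched noncoding RNAs, replication-dependent histones, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, immediate early genes, naive T cell and quiescence, effector and memory T cell, T cell receptor signalling, cell death and survival, p53 targets, type I interferon response, unfolded protein and amino acid stress, heat shock, proliferation, and markers of B cells, CD4 and regulatory T cells, NK cells, myeloid cells, dendritic cells, erythroid cells and platelets. Lists with at least 5 tested genes were tested with camera, two-sided, with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The rule named Nxf1, then the 12 genes with the largest log2 fold change in each direction among those with adjusted p under 0.05, a mean log2 CPM of at least 2 and the same direction in all 3 batches, and up to 4 genes with the smallest p in each list. Some genes that the rule names are not reported here. A few single-exon genes and gene families were chosen after their values were seen, which is said where they appear.

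Exon numbers and GC content came from the longest transcript of each gene in GENCODE release M21 (GRCm38), joined by Entrez identifier. They were found for 11096 of the 12570 tested genes (88.3%). Gene coordinates and current symbols came from a RefSeq table of the same assembly, which matched 25260 of the 27152 identifiers. Spearman correlations between these features and the log2 fold change run across genes, which are not independent replicates, so they carry no p-value. The annotation was parsed in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.

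The tests were run first on simulated counts with the library sizes of these samples, over 12570 genes with 50 genes changed at each fold. Means, batch differences and the spread of counts were taken from the fit with batch as the block, which favours that fit in the simulation. Without a block, edgeR recovered 4% of genes raised 1.2-fold, 80% of those raised 1.5-fold, and 98% of those changed 2-fold up or 0.5-fold down, and it called 0 of the unchanged genes. With the block it recovered 76% at 1.2-fold and 100% at the other folds, and called 9 unchanged genes. A list of 30 genes raised 1.25-fold was called by camera with the preset correlation, together with 0 of 99 unchanged lists, and was missed with an estimated correlation. The unchanged lists were random genes drawn independently of each other, so this does not give camera's error rate for lists whose members vary together. In the real samples the estimated correlation of a list ran from -0.0466 to 0.761. Other alternatives were DESeq2 1.42.0 (size factors and Wald test), upper-quartile factors, limma-voom with and without quality weights, other filters on low counts, and leaving out each library and each batch in turn. Chosen after seeing the data were the removal of Rn45s, other definitions of the single-exon set, and exon number without the interferon and immediate early genes.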

Results

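Cytoplasmic polyadenylated RNA was sequenced from naive CD8 T cells, the resting cytotoxic T cell precursors that have not met antigen. The cells were sorted from the spleens of 3 male mice carrying 1 copy of the Nxf1 C587R allele and of 3 wild-type littermates, and were processed in 3 batches of 1 mouse per genotype. NXF1 is the main receptor that carries mRNA through the nuclear pore into the cytoplasm, and C587R replaces a cysteine of the protein with an arginine. Total counts were 17596704, 20367206 and 20047830 in the mutant libraries of batches 1, 2 and 3 and 19142298, 19371891 and 19332029 in the wild-type libraries. At this depth 15637 to 15893 genes had at least 1 count in a library, and 12570 genes were tested. Levels below are CPM, as mean ± SD of 3 mice. The comparison asks which cytoplasmic transcripts differ between the genotypes.

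Transcripts of Nxf1 itself (chromosome 19, 8757103 to 8770910, GRCm38, 20 exons) stood at 313 ± 5.49 CPM in the mutants and 320 ± 8.29 CPM in the wild types. The log2 fold change was -0.03 with a standard error of 0.03 (edgeR adjusted p = 0.841), which lies within the spread between mice. The allele changes an amino acid and need not change the transcript level, so this value does not check the genotype labels.

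Of the 12570 genes tested, 457 were higher and 231 were lower in mutant cells in edgeR's quasi-likelihood test. All 688 moved the same way in each of the 3 batches. Most changes were small: 71 of the higher genes exceeded a log2 fold change of 1 and 31 of the lower genes fell below -1. The first principal component (40.7% of the variance) separated the genotypes. With batch as the block, 1491 genes were higher and 1251 lower, including 684 of the 688, and the share of higher genes among all called was 54.4% in place of 66.4%. Fewer were called without mutant replicate 2 (294 higher, 105 lower), without wild-type replicate 2 (246 and 106), without batch 1, whose labels carry crossed numbers (276 and 90), and without batch 2 (94 and 21). With the genotypes of batch 1 exchanged, 0 genes passed, and 106 had an unadjusted p under 0.05 in edgeR, while 5 gene lists passed camera. Rn45s, the ribosomal RNA precursor, took a larger share of the counts in the mutant of each batch (3.94% against 3.31%, 3.59% against 2.66% and 2.63% against 2.32%), a log2 fold change of 0.33 that did not pass without a block (adjusted p = 0.471) and passed with it (2.34e-07).

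Of the 12 called genes with the largest increase at a mean log2 CPM of at least 2, the 6 in this paragraph were grouped by gene family after their values were seen, and the grouping was not tested. Iigp1, an immunity-related GTPase that acts against intracellular pathogens, rose from 54.2 ± 3.71 to 214 ± 5.52 CPM, a log2 fold change of 1.98 with a standard error of 0.06 (edgeR adjusted p = 1.74e-08). The gene has 3 exons and lies on chromosome 18 at 60373616 to 60392634 (GRCm38). Irgm2 (3 exons, chromosome 11, 58214977 to 58222783), of the same GTPase class, rose from 158 ± 16.9 to 478 ± 22.2 CPM, and Gm12185, listed in RefSeq with the synonym Irgb2b1, rose from 63.6 ± 2.47 to 191 ± 13.9 CPM. Their log2 fold changes were 1.60 and 1.59. Gm4070, listed with a synonym of the very large interferon-inducible GTPases, rose from 647 ± 78.2 to 1873 ± 281 CPM (log2 1.53). Gm14446 and I830012O16Rik, now named Ifit1bl1 and Ifit3b, have overlapping loci on chromosome 19 and rose by 1.75 and 1.51 on the log2 scale. Copies in these GTPase and Ifit families resemble each other closely, so the split of reads among them is uncertain.

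The other genes of this group belong to other gene families, which does not say whether interferon induces them. Ly6a, which encodes the surface protein Sca-1, rose from 51.4 ± 7.13 to 182 ± 16.3 CPM (log2 1.83, edgeR adjusted p = 4.59e-06). Irf4, a transcription factor induced by T cell receptor signals, rose from 5.67 ± 0.352 to 17.2 ± 1.45 CPM (log2 1.60, adjusted p = 3.75e-06). Casp1, the inflammatory caspase, rose from 2.12 ± 0.538 to 6.02 ± 1.56 CPM, and Pls3, an actin-bundling plastin on chromosome X, from 1.62 ± 0.743 to 8.03 ± 2.44 CPM (log2 2.30). Pls3 lost its call without wild-type replicate 1 and without batch 1 (its edgeR adjusted p with all libraries was 0.0082). The largest fitted values of this group were those of Xlr3b and Xlr3a, near-identical X-linked lymphocyte-regulated genes whose reads cannot be assigned to 1 copy with certainty. Xlr3b stood at 17.1 ± 5.17 against 2.12 ± 1.51 CPM (log2 3.01, adjusted p = 0.0289) and Xlr3a at 13.8 ± 2.62 against 2.24 ± 1.78 CPM (log2 2.62, adjusted p = 0.0403). Xlr3a no longer passed with batch as the block (edgeR adjusted p = 0.0549). Both lost their calls without mutant replicate 1, mutant replicate 3, wild-type replicate 1 or wild-type replicate 2, and Xlr3a also without mutant replicate 2. They also lost them without batch 1, without batch 2 and with no filter on low counts.

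Of the 12 called genes with the largest decrease at a mean log2 CPM of at least 2, Nrp2, a receptor for semaphorins and VEGF, fell most, from 17.9 ± 2.55 to 4.82 ± 2.37 CPM (log2 -1.89, edgeR adjusted p = 0.0257). It lies on chromosome 1 at 62703317 to 62818692 (GRCm38) and has 16 exons, and its call was lost without mutant replicate 1, without any 1 of the 3 wild-type replicates, without batch 1 and with no filter on low counts. Nt5e, which encodes the ectonucleotidase CD73, fell from 15.7 ± 3.18 to 5.79 ± 0.456 CPM (log2 -1.44, adjusted p = 0.000133). G0s2, an inhibitor of triglyceride lipase, and Man1c1, a Golgi mannosidase, had log2 fold changes of -1.24 and -1.10. Rcn3, a calcium-binding protein of the endoplasmic reticulum, fell from 75.8 ± 8.83 to 36.6 ± 5.77 CPM (log2 -1.05). The remaining genes were Baiap3 (log2 -1.25), the phosphatase gene Ppm1j (-1.25), the tetraspanin gene Tspan9 (-1.24), Armcx4 (-1.05), Arhgap29 (-1.01), Snurf (-0.94) and 1110001J03Rik, now named Fmc1 (-0.91). Snurf shares transcripts with Snrpn, so its reads are uncertain. The Arhgap29 call was lost without mutant replicate 2, the Snurf call without batch 1, and those of Ppm1j, Armcx4 and 1110001J03Rik without batch 2.

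**Figure D1:**
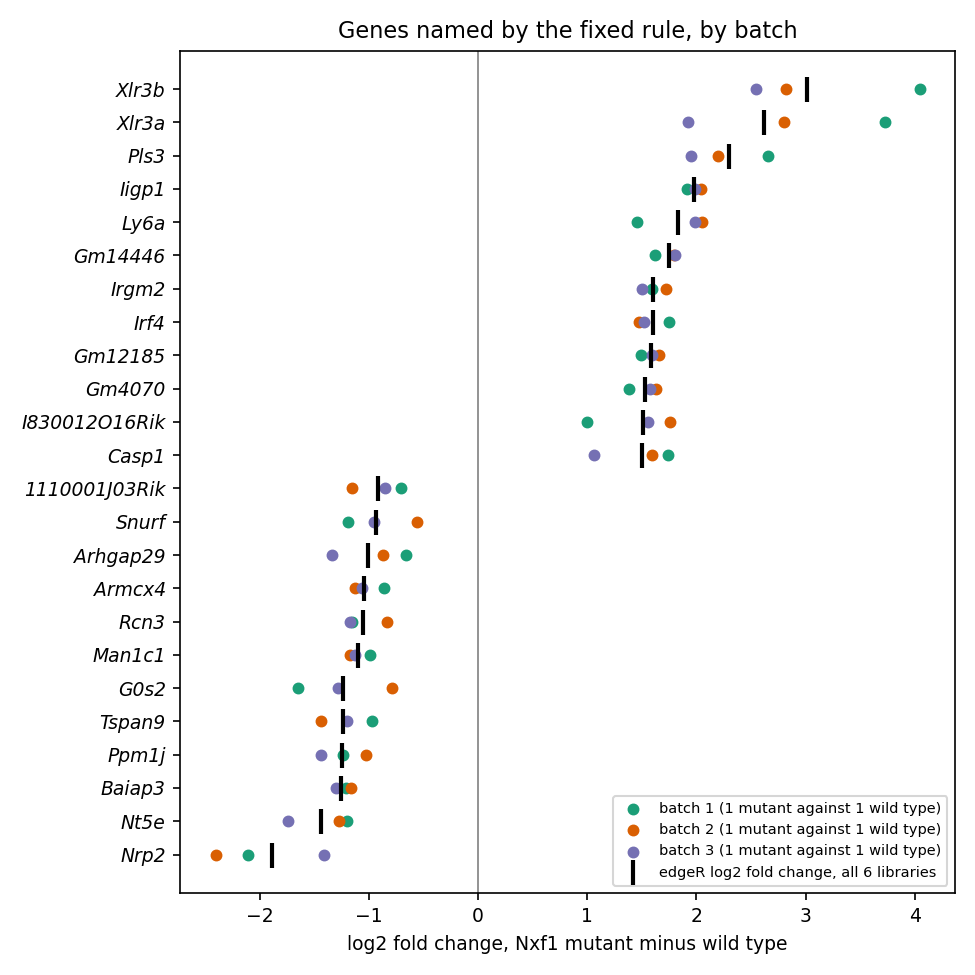
Log2 fold change (horizontal axis, mutant minus wild type) of 24 called genes, the 12 with the largest change in each direction at a mean log2 CPM of at least 2, 1 row per gene. Points are the 3 batches, each 1 mutant against 1 wild-type library, and black ticks are the edgeR values over all 6 libraries; every point of a gene lies on the same side of 0, with Iigp1 between 1.91 and 2.04.

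Of 44 tested genes of the type I interferon list, 24 were higher, 0 were lower and 20 did not pass, and 33 were higher when adjusted over the list alone. The median log2 fold change was 0.46, with 0.35, 0.54 and 0.42 in the 3 batches, and 23 genes were higher without batch 1. Igtp, an immunity-related GTPase, rose from 474 ± 18.3 to 930 ± 16.8 CPM (log2 0.97), Rtp4 from 38.5 ± 2.87 to 82.4 ± 6.84 CPM (log2 1.10) and Slfn1 to 479 ± 8.85 CPM (log2 0.71), with edgeR adjusted p between 1.04e-06 and 2.81e-05 for the 3 genes. Camera gave an adjusted p of 1.38e-40 with the preset correlation of 0.01. The adjusted p was 0.213 with an estimated correlation and 0.549 with that and the block, and fry, which asks whether the members move 1 way on balance, gave 0.0364, and 0.0528 with batch as the block.

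Immediate early genes, which respond within minutes to receptor signals or to handling of the cells, rose in 11 of 34 tested and fell in 0. Adjusted over the list alone 17 were higher, with batch as the block 20, and without batch 1 the count was 8 (19 with the block). The median log2 fold change was 0.25, with 0.32, 0.28 and 0.23 in the 3 batches. Egr2, an early growth response transcription factor, rose from 19.2 ± 1.55 to 36.2 ± 2.73 CPM (log2 0.91) and Egr1 by 0.58 on the log2 scale (standard error 0.07). Zfp36, which promotes decay of cytokine mRNAs, rose by 0.51 and Ier5 by 0.42 on the log2 scale. Camera gave an adjusted p of 1.44e-14 with the preset correlation, 0.0693 with an estimated correlation and 0.549 with that and the block. Fry gave 0.00553, and 0.0463 with batch as the block.

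Proliferation genes were higher in 6 of 28 and lower in 0, with a median log2 fold change of 0.38 and batch medians of 0.45, 0.23 and 0.48, beside 0.50, -0.21 and 0.35 for B cell markers. Top2a, the topoisomerase of dividing cells, rose from 9.13 ± 0.337 to 17.6 ± 3.02 CPM (log2 0.95) and E2f1 by 0.87, Aurkb by 1.56 and Mcm2 by 0.29 on the log2 scale. Aurkb was a low transcript at 1.22 ± 0.0891 against 0.409 ± 0.0486 CPM. Adjusted over the list alone 10 were higher and with batch as the block 12. Without batch 1 the count was 1 in the fit without a block and 10 with it. E2f1 lost its call without wild-type replicate 2, Mcm2 without mutant replicate 2, E2f1 also in DESeq2 with the block, and Aurkb in both DESeq2 fits. Camera's adjusted p was 1.82e-07 with the preset correlation and 0.474 with an estimated correlation, and fry gave 0.0525, and 0.105 with batch as the block.

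Of 25 tested SR and SR-like splicing factors 2 were lower and 0 higher. Srsf5, a serine- and arginine-rich splicing factor, fell from 433 ± 20.2 to 369 ± 7.70 CPM (log2 -0.23, edgeR adjusted p = 0.031). Sfrs18, now named Pnisr, fell by 0.24 on the log2 scale (adjusted p = 0.0363). The Srsf5 call was lost without any 1 of the 6 libraries and the Sfrs18 call without any 1 except mutant replicate 3. Adjusted over the list alone 0 were higher and 3 lower. Clk1 (log2 -0.24) and Luc7l (log2 -0.16) did not pass without a block, and with batch as the block 16 genes were lower, both of these included, and 1 was higher. The median was -0.12, with -0.12, -0.09 and -0.11 in the 3 batches. Camera's adjusted p was 0.00195 with the preset correlation and 0.641 with an estimated correlation, and fry gave 0.151 (0.0528 with batch as the block). Without batch 1, 0 genes of the list passed in the fit without a block, while 11 were lower and 1 was higher with the block.

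Genes of naive and quiescent T cells were higher in 6 of 27 and lower in 0. Slfn2, a Schlafen gene required for T cell quiescence and also inducible by interferon, rose from 313 ± 19.4 to 513 ± 28.0 CPM (log2 0.71). Dapl1 rose by 0.42 and Ly6c1, a surface protein that interferon also induces, by 0.24 on the log2 scale. Bcl2, the survival factor, had a log2 fold change of 0.46 and passed without a block (edgeR adjusted p = 0.00537) but not with it (0.118). The Ly6c1 call was lost without mutant replicate 2 or 3 and without wild-type replicate 2 or 3. Reads of Ly6c1 and its near-identical neighbour Ly6c2 may not be separable. Adjusted over the list alone 8 were higher and 1 lower, and with batch as the block 11 were higher and 4 lower. Without batch 1, 3 were higher in the fit without a block, and 9 were higher and 5 lower with it. The median was 0.07, with 0.07, 0.06 and 0.06 in the 3 batches, and camera's adjusted p of 0.0217 became 0.664 with an estimated correlation. Fry gave an adjusted p of 0.161 without a block and 0.0463 with batch as the block. The list also lost its camera call without mutant replicate 3 (0.143) or wild-type replicate 1 (0.156).

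Unfolded protein and amino acid stress genes were higher in 3 of 24 and lower in 0, with the same count adjusted over the list alone and 11 higher with batch as the block. The 3 were Hspa5, the main chaperone of the endoplasmic reticulum (log2 0.27), Edem1 (0.24) and Sdf2l1 (0.36), and the amino acid synthesis gene Phgdh stood at log2 0.22 without passing (edgeR adjusted p = 0.117) and passed with batch as the block (0.000323). The Sdf2l1 call was lost without any 1 of the 6 libraries, with upper-quartile factors and in both DESeq2 fits. The Edem1 call was lost without any 1 library except wild-type replicate 3, and that of Hspa5 without mutant replicate 1 or 2 or wild-type replicate 2. The list median was 0.09, and 0.09, 0.09 and 0.11 in the 3 batches. Camera's adjusted p was 0.0217 with the preset correlation and 0.623 with an estimated correlation, and fry gave 0.0572, and 0.0463 with batch as the block. With the preset correlation camera's adjusted p was 0.0969 without mutant replicate 1, 0.0574 without mutant replicate 2, 0.105 without wild-type replicate 3 and 0.0674 without batch 1. Without batch 1, 0 genes passed in the fit without a block and 8 were higher with it.

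**Figure D2:**
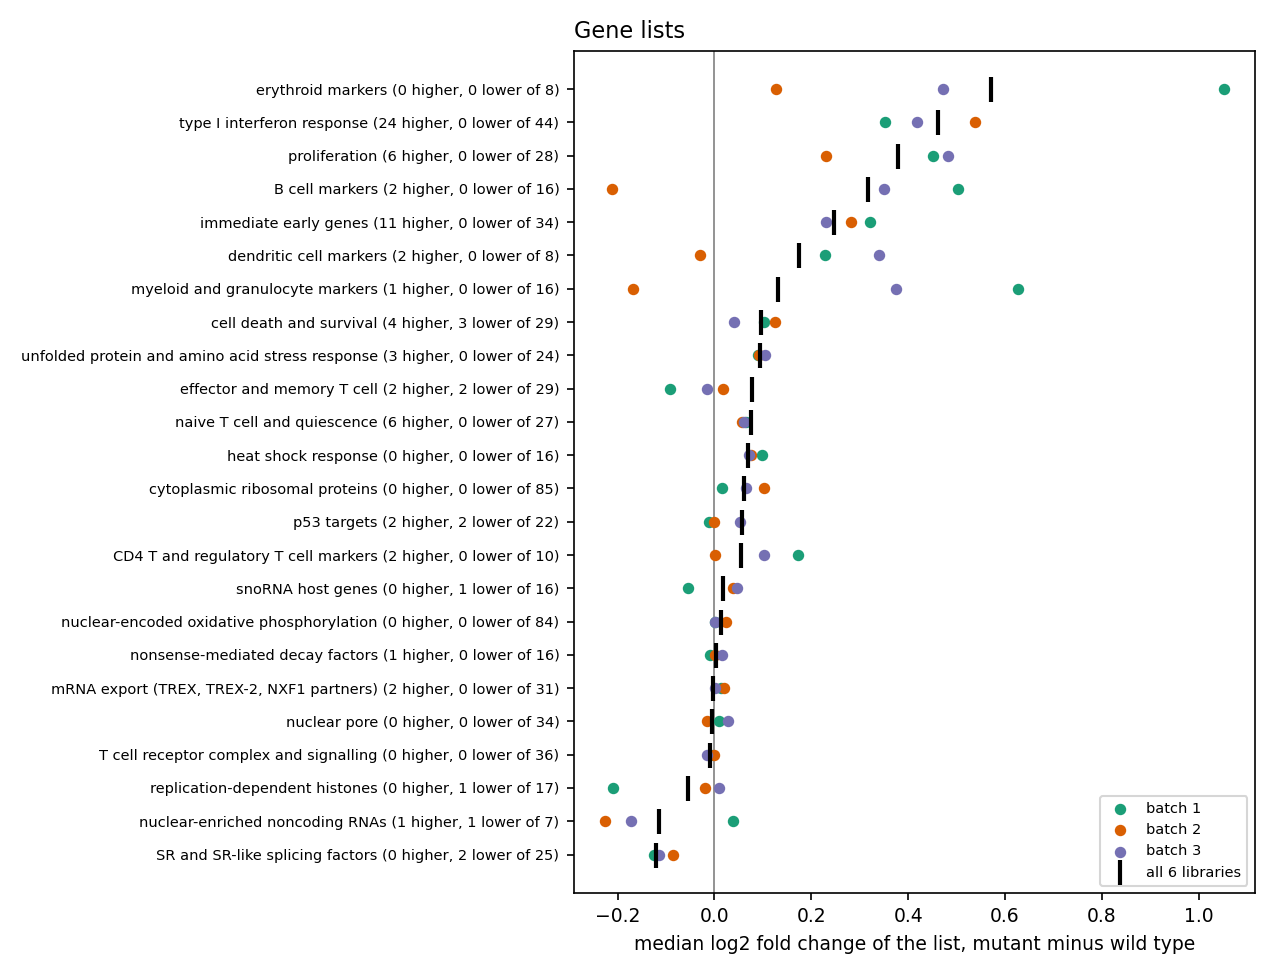
Median log2 fold change (horizontal axis, mutant minus wild type) of the 24 gene lists with at least 5 tested genes, 1 row per list with its counts of higher and lower genes. Points are the 3 batches and black ticks all 6 libraries; the type I interferon list sits at 0.46 with 24 of 44 genes higher, while B cell, dendritic and myeloid markers lie below 0 in batch 2 and above 0 in batches 1 and 3.

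Of the 24 lists tested, the 6 above passed camera with the preset correlation, 0 passed with an estimated correlation, and fry called 2 without a block. With batch as the block, fry called the immediate early, naive T cell and unfolded protein lists (adjusted p = 0.0463 for each) and not the interferon list (0.0528). Genes of the mRNA export machinery were 2 higher of 31: Alyref2, a single-exon export adaptor (log2 0.68, edgeR adjusted p = 0.00188), and 2500003M10Rik, now named Chtop, a partner of NXF1 loading (log2 0.24, adjusted p = 0.0201). The latter call was lost without any 1 mutant replicate or wild-type replicate 2. Nxt1, which binds NXF1, stood at log2 0.29 and Pcid2 at -0.14 without passing, and both passed with batch as the block, where 5 genes were higher and 4 lower. Among 34 nuclear pore genes 0 passed (block, 4 higher and 2 lower), with Nup62 at log2 0.22, Nup35 at -0.29, Ran at 0.18 and Nup214 at 0.15, and these 4 passed only with the block. Of 16 nonsense-mediated decay factors, 1200011M11Rik, now named Smg8, was higher (log2 0.34, adjusted p = 0.011), a call lost without wild-type replicate 2. Casc3 (-0.16) passed with the block, where 2 were higher and 1 lower, while Magohb (-0.19) and Smg5 (0.07) passed in neither fit. Of 16 snoRNA host genes D7Ertd715e, now named Snhg14, was lower (log2 -0.97, adjusted p = 0.0386), with -1.32, -0.15 and -1.32 in the 3 batches. Its call was lost without any 1 library except wild-type replicate 2, in limma-voom without the block and in DESeq2 with it. The hosts Zfas1 (0.22), Snhg15 (0.22) and Snhg20 (-0.21) passed with the block, where 3 were higher and 2 lower.

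Nuclear-enriched noncoding RNAs went both ways: of 7, Tug1 rose from 208 ± 4.64 to 296 ± 22.6 CPM (log2 0.51, edgeR adjusted p = 0.000508) and Neat1, the scaffold of paraspeckles, fell from 808 ± 82.2 to 591 ± 48.6 CPM (log2 -0.45, adjusted p = 0.00739). The Neat1 call was lost without mutant replicate 2 or wild-type replicate 2. Firre (log2 -0.37) passed with the block and was the second lower gene adjusted over the list alone, and Pvt1 (0.16) passed in neither fit. Of 69 listed replication-dependent histone genes only 17 had enough counts to be tested in these libraries of polyadenylated RNA. Among the 17, Hist2h2be was lower (log2 -0.67, edgeR adjusted p = 0.017), a call lost without mutant replicate 2 or wild-type replicate 2. Hist3h2a (-0.27), Hist3h2ba (-0.73) and Hist2h2aa2 (-0.65) did not pass. Of 85 ribosomal protein genes 0 passed. With the block 22 were higher and 1 lower, with Rps29 at -0.22 and Rplp0 (0.21) and Rps20 (0.16) above 0, the list median was 0.06 and camera's adjusted p moved from 0.131 to 0.043, which became an adjusted p of 0.755 with an estimated correlation and the block. Without a block the ribosomal list also passed without wild-type replicate 1 (6.2e-05), mutant replicate 3 (0.000552) or batch 1 (0.0209), and with the genotypes of batch 1 exchanged (0.000102). Of 84 oxidative phosphorylation genes 0 passed (block, 6 higher and 1 lower). Ndufa10 (0.16) and Ndufv3 (0.14) passed with the block, and Gm3244 (-0.16) and Atp5k (-0.18) in neither fit.

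Effector and memory genes were 2 higher and 2 lower of 29 (5 and 6 adjusted over the list alone, 5 and 10 with the block). The chemokine receptor gene Cxcr3 fell from 31.2 ± 4.57 to 21.1 ± 1.87 CPM (log2 -0.57) and Il18r1, an interleukin 18 receptor chain, from 191 ± 28.6 to 130.5 ± 10.1 CPM (log2 -0.55), while Tnfrsf9 (0.49) and Ly6c2 (0.26) were higher. The Cxcr3 call was lost without mutant replicate 2 and that of Il18r1 without mutant replicate 2 or 3 or wild-type replicate 3. The Tnfrsf9 call was lost without any 1 library except mutant replicate 3, in both DESeq2 fits and in limma-voom without the block, and that of Ly6c2 without any 1 except mutant replicate 1. Among 36 genes of T cell receptor signalling 0 passed (block, 5 higher and 5 lower), with Trat1 at -0.51, Bcl10 at 0.18, Cd2 at -0.12 and Cd6 at -0.14, which passed with the block. Cell death and survival genes were 4 higher and 3 lower of 29 (6 and 3 adjusted over the list alone, 10 and 3 with the block). Without batch 1 they were 1 and 0, and 9 and 3 with the block. Among the called genes over all libraries were Bcl2, Pmaip1 (log2 0.78) and Bak1 (0.29) above and Fas (-0.35) below. Of 22 p53 targets 2 were higher and 2 lower: Pmaip1 and Btg2 (0.36) against Fas and Bbc3 (-0.44). The counts were 2 and 3 adjusted over the list alone and 4 and 2 with the block. Without batch 1 they were 1 and 1, and 4 and 3 with the block. Calls were lost without wild-type replicate 2 for Pmaip1, Bak1, Fas, Btg2 and Bbc3, without mutant replicate 2 for Bak1 and Bbc3, without mutant replicate 1 or 3 for Fas and Bbc3, and without wild-type replicate 1 for Bbc3. Bbc3 also lost its call at a mean CPM of at least 5, in both DESeq2 fits and in limma-voom without the block. Of 16 heat shock genes 0 passed (block, 4 higher), with Bag3 at 0.38, Dnajb1 at 0.17, Hspa8 at 0.15 and Hspd1 at 0.12, which passed with the block. Adjusted over the list alone, the counts not given were the same as over all genes. The effector list had a median of 0.08 and a mean of 0.05 while camera's direction was down, the snoRNA hosts a median of 0.02 and a mean of -0.07, the export list a median of -0.0032 and a mean of 0.03, and the nuclear pore list a median of -0.0043 and a mean of 0.0029 with camera's direction down.

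Markers of other spleen cells had higher medians in batches 1 and 3 than in batch 2. B cell markers were 2 higher of 16: Ighm, the immunoglobulin heavy chain, rose from 320 ± 8.84 to 394 ± 9.60 CPM (log2 0.30, edgeR adjusted p = 0.00562) and Bank1 from 4.92 ± 0.169 to 7.24 ± 0.640 CPM. The Bank1 call was lost without mutant replicate 1 or 3 or wild-type replicate 2 and in both DESeq2 fits. Cd79b (log2 0.35) and H2-Aa (0.36) passed with the block only, where 5 were higher. The list medians were 0.50, -0.21 and 0.35 in batches 1, 2 and 3, and 0.63, -0.17 and 0.37 for myeloid markers. Of 16 myeloid markers Ctss was higher (log2 0.23) and adjusted over the list alone 3 were, with Ccr2 (0.97) and Itgam (0.50) passing in the fit with the block, where 4 were higher and 1 lower, and Cst3 (-0.17) in neither. Of 8 dendritic cell markers Irf8 (log2 0.57) and Bst2 (0.37) were higher, and Bst2 is also on the interferon list. Ccr9 (-0.29) passed with the block, where 3 were higher and 1 lower, and Cd83 (0.30) in neither fit. Of 10 markers of CD4 and regulatory T cells Ikzf2 (log2 0.75) and Icos (0.41) were higher, and Cd40lg (-0.87) and Zbtb7b (-0.93) were lower with the block only. The Ctss call was lost without any 1 mutant replicate or wild-type replicate 2, and the Icos call without any 1 library except wild-type replicate 3. The CD4 list median was 0.06 and its mean -0.0074. Without batch 2 the calls of Ighm, Bst2 and Ikzf2 were lost, as were those of Aurkb, Zfp36, Ier5, Dapl1, Alyref2 and Tug1 above. The Ikzf2 and Aurkb calls were also lost without batch 1. There 0 of the 10 markers of CD4 and regulatory T cells were higher without a block, and 2 were higher and 2 lower with it.

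Erythroid markers had a median log2 fold change of 0.57 over 8 genes, with batch medians of 1.05, 0.13 and 0.47, and 0 passed (1 adjusted over the list alone). Hbb-b1, a haemoglobin gene with near-identical copies, stood at 13.6 ± 5.81 against 7.38 ± 3.40 CPM and passed with the block (edgeR adjusted p = 1.6e-08), as did Car2 (log2 0.42). Hba-a1 (0.97) and Ermap (-0.80) passed in neither fit, and with the block 4 were higher and camera's adjusted p moved from 0.104 to 0.0127, which became an adjusted p of 0.755 with an estimated correlation and the block. None of the 5 lists of other cells in this and the preceding paragraph passed camera without the block over all 6 libraries and the main filter on low counts, with adjusted p of 0.104 for B cells, 0.381 for CD4 T cells, 0.353 for myeloid cells, 0.127 for dendritic cells and 0.104 for erythroid cells. At a mean CPM of at least 5, B cell (0.0051), CD4 T cell (0.0446) and erythroid markers (0.0446) passed, and with no filter on low counts dendritic (0.0236) and erythroid markers (0.00475). Without batch 2, B cell, myeloid, dendritic and erythroid markers all passed (0.000168, 0.000718, 0.0218 and 2.52e-05). B cell markers also passed without mutant replicate 2 (0.00487) or wild-type replicate 2 (0.0183), and myeloid (0.0183) and dendritic markers (0.0471) without wild-type replicate 2. Erythroid markers also passed without mutant replicate 2 (3.46e-05), wild-type replicate 3 (0.00763) or batch 3 (0.0172). NK cell markers (4 tested, Fcer1g, Gzma, Cd244 and Tyrobp) and platelet markers (3 tested, Itgb3, Gp1ba and Itga2b) were too few for a test of the list, and 0 of them passed. No row of the tables matched the mitochondrially encoded list.

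Genes with few exons were more often higher in the mutants than genes with many exons. Among 283 genes with 1 exon, 19.4% were higher and 2.83% lower, and among 508 genes with 2 exons 21.7% were higher and 2.36% lower. The share of higher genes was 8.76% at 3 exons, 3.53% at 4 to 5, 2.19% at 6 to 10, 1.74% at 11 to 20 and 1.39% above 20 exons, where 2.50% were lower. With batch as the block these shares were 32.9% higher and 5.65% lower at 1 exon, 7.38% and 13.2% at 11 to 20 exons, and 11% and 14.2% above 20 exons. Median log2 fold changes went from 0.12 and 0.14 at 1 and 2 exons to -0.03 at 11 to 20 exons and -0.02 above 20. Within each batch the median was higher at 1 exon than at 11 to 20 exons, with of 0.12, 0.15 and 0.14 at 1 exon and -0.02, -0.03 and -0.02 at 11 to 20 exons in batches 1, 2 and 3.

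**Figure D3:**
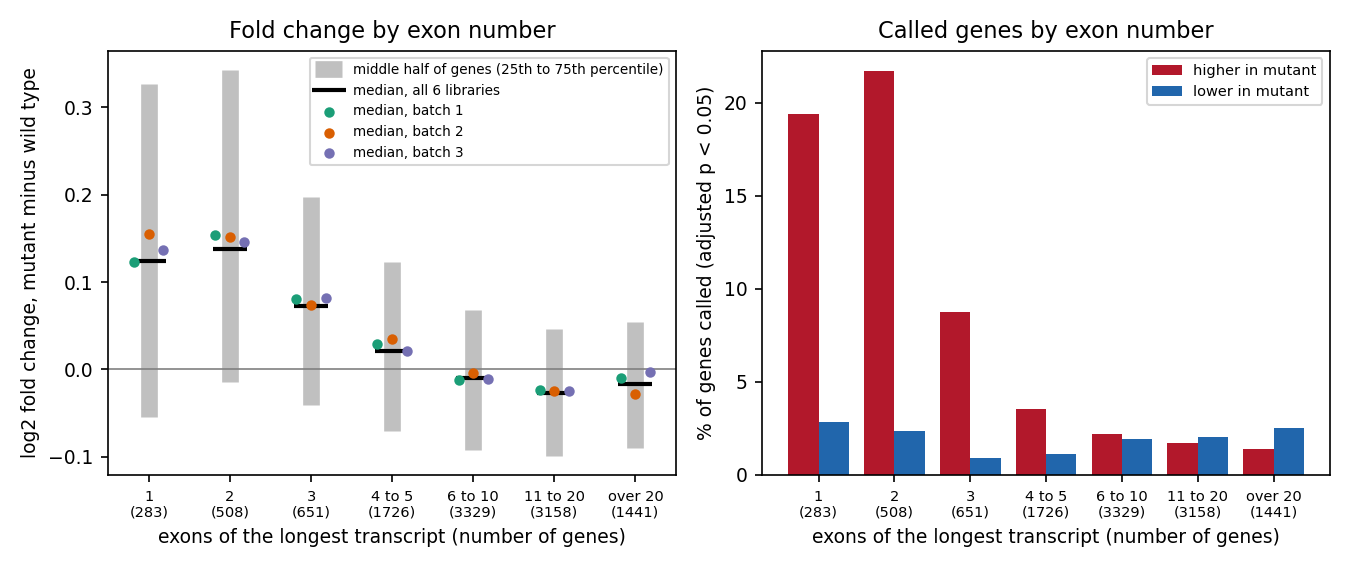
Left, median log2 fold change (mutant minus wild type) by the number of exons of the longest transcript, with the middle 50% of genes in grey and the medians of the 3 batches as points. Right, the percentage of tested genes called higher or lower by edgeR in each class; 19.4% of single-exon and 21.7% of 2-exon genes were higher against 1.39% of genes with over 20 exons.

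Across genes, which are not independent replicates, Spearman's rho between exon number and log2 fold change was -0.193, and -0.154, -0.203 and -0.152 within the 3 batches. For transcript length rho was -0.0244, with 0.0243, -0.0552 and -0.0289 in the batches. For GC content it was -0.0244, with -0.116, -0.0149 and 0.0652, so neither relation kept its sign within batches. Other groupings of the same 6 libraries also gave correlations with exon number, as large as 0.304 in absolute value.

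Single-exon genes included several well measured transcripts, chosen here after their values were seen. Lpar6, a lysophosphatidic acid receptor (chromosome 14, 73237891 to 73240358, GRCm38), rose from 92.1 ± 0.817 to 172 ± 4.60 CPM (log2 0.90, edgeR adjusted p = 1.36e-06). Zrsr1, a retrogene related to a splicing factor, rose from 43.1 ± 2.25 to 86.3 ± 2.42 CPM, and Hexim1, an inhibitor of transcription elongation, from 43.5 ± 1.37 to 77.9 ± 2.33 CPM. Klhl9 and Zfp830 rose by 0.85 and 0.77 on the log2 scale. Of the 283 genes 55 were higher and 8 lower (67 and 11 adjusted over the set alone, 93 and 16 with batch as the block, 35 and 4 without batch 1). Their median log2 fold change was 0.12 against -0.0053 for 10813 genes with several exons. Camera gave p = 4.45e-10 with the preset correlation and p = 0.00556 with an estimated correlation.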

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

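The alternatives were fixed before the data were examined, except the removal of Rn45s and of whole gene groups and the other single-exon definitions, under which the single-exon set kept its call and rho for exon number its sign; without Rn45s 458 genes were higher and 228 lower, and all 74 named calls held. The direction of the single-exon median held in all alternatives run (0.05 to 0.16), and Nxf1 passed in none (adjusted p from 0.494 to 1). With batch as the replicate block, in the pairing the labels give, edgeR called 1491 genes higher and 1251 lower, and limma-voom with quality weights and the block 1476 and 1228; the common coefficient of variation fell from 0.072 to 0.0276. Apart from calls given with the results, the block changed none of the calls named there. Leaving out 1 library gave 246 to 443 genes higher, 105 to 189 lower and 5 to 9 lists, and rho from -0.149 to 0.109 for length, from -0.259 to -0.110 for exon number and from -0.181 to 0.087 for GC content. Without batch 1 the counts were 276 and 90, without batch 2 they were 94 and 21 with 10 lists, and without batch 3 they were 484 and 221; fewer libraries enter these fits. Exon number gave rho of -0.12 with no filter on low counts, -0.235 at a mean CPM of at least 5 and -0.229 at a mean CPM of at least 20. At a mean CPM of at least 5 there were 10 lists past the threshold, and the effector and memory list turned to -0.16 (adjusted p = 0.0353), on fewer genes. Lists past the threshold numbered 0 with an estimated correlation, 0 with an estimated correlation and the replicate block, and 2 with fry without a block. With the block, fry called the immediate early, naive T cell and unfolded protein lists. With the genotypes of batch 1 exchanged, 0 genes were higher and 0 lower in edgeR (98 with an unadjusted p under 0.05 in the fit with the block), yet camera called the interferon, immediate early, ribosomal, myeloid and erythroid lists and the single-exon genes (median 0.05). In that fit rho was -0.0666 for length, -0.139 for exon number and 0.114 for GC content, and signs turned for D7Ertd715e (0.044), Bbc3 (0.045), myeloid markers (-0.40, adjusted p = 0.00616) and erythroid markers (-0.16, adjusted p = 0.0434). Where no construction of the fit is named, the cause was not tested. Of 74 genes named as passing, 72 passed with the block, 73 with upper-quartile factors, 71 with no filter between 50 and 65 without any 1 library, and 48, 36 and 67 without batches 1, 2 and 3. Of simulated 1.2-fold changes 4% were recovered without a block and 76% with it, and depth was not varied. The simulated counts were drawn from the fit with the block, which favours it.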

Other observations

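Tests of gene families, of nuclear RNAs, of immediate early genes by exon class and of other splits for the number of genes called and for exon number were chosen only after those results had been seen. The fit with batch 1 exchanged was planned, but what it would show under a swap was written down only afterwards. The families below were not tested for enrichment. All 11 tested guanylate-binding protein genes rose, with a median log2 fold change of 0.69 and 0.69, 0.77 and 0.60 in the 3 batches, and 1 of them was on the fixed interferon list. Gbp11 rose from 15.2 ± 0.875 to 33.8 ± 1.35 CPM and Gbp10 from 204 ± 18.2 to 383 ± 30.5 CPM. Of 8 genes grouped here as the Gvin1 cluster of very large GTPase genes on chromosome 7, 7 were higher, with a median of 1.38, and of 7 genes picked by symbol as immunity-related GTPases 6 were, with a median of 0.97, counting Igtp of the fixed list and leaving out Gm12185. The Tgtp1 transcript rose from 917 ± 37.3 to 1793 ± 11.9 CPM, shared with its near-identical copy Tgtp2. Of 6 genes now named Ifit 5 were higher (3 of the 6 on the fixed list), of 7 Schlafen genes 3 (3 of the 7 on the list), and of 8 Gimap genes 3. With batch as the block 4 Ifit, 6 Schlafen and 6 Gimap genes were higher. Genes of BTB zinc finger proteins, with a median of 3 exons, were higher in 8 of 38 and lower in 0 (15 and 1 with batch as the block). Among the 8 were Zbtb1 (from 60.9 ± 6.83 to 103 ± 7.37 CPM) and Zbtb5 (from 23.5 ± 2.41 to 38.4 ± 2.01 CPM).

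Among other X-linked lymphocyte-regulated genes, Xlr3c, the third Xlr3 copy, had a log2 fold change of 2.94 (2.27 ± 0.888 against 0.290 ± 0.195 CPM, edgeR adjusted p = 0.00339), while Xlr4a stood at 0.10 (130 ± 9.22 against 121 ± 5.98 CPM, adjusted p = 0.492). Snurf and D7Ertd715e, which overlap on chromosome 7 (59982495 to 60005199 within 59272737 to 60450177, GRCm38), had log2 fold changes of -0.94 and -0.97, the latter with a call lost without most single libraries. Among 34 immediate early genes the median excess over genes of the same exon class was 0.21 on the log2 scale.

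Single-exon genes were higher in the mutants, with a median 0.129 above that of all other tested genes on the log2 scale, those without an exon number included. Genomic DNA in the mutant libraries would raise silent olfactory receptor genes as much per kb, but their gain was 0.0155 of that of single-exon genes (0.0276 against 0.0218 CPM per kb). Length, GC content and expression level left a median of 0.114 after regression on them, so the tables argue against these as the whole cause. The interferon and immediate early lists held only 5 genes of the set, and without them the median was 0.116. Those 5 genes thus do not carry the median, but any gene outside the lists that interferon induces stayed in the set. Less nuclear RNA in the mutant fractions stays open, because 3 of 7 nuclear-enriched noncoding RNAs were lower in all 3 batches while Tug1 was higher, and the 10 splits of the 6 libraries are too few for a share under 0.05 (0.129 in 1 split, the labelled one, against 0.0869 in the highest other). An effect of the Nxf1 genotype on export of mRNAs that undergo little splicing is a candidate explanation, untested here because no nuclear fraction was analysed here.

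Interferon response genes were higher in the mutants by a median of 0.46 on the log2 scale, and some of them have few exons, yet their median excess over other genes of the same exon class was 0.463, and 13 of 30 with over 5 exons were higher against 7 of 7 with 3 or fewer. More B, myeloid or dendritic cells in the mutant sort would bring their markers along. The 39 markers of these cells gained 102 CPM net against 2560 CPM for the interferon genes, a ratio of 0.0399 (0.0111 without Ighm). The net sum includes a fall of Ccr9, also on the naive T cell list, from 166 to 136 CPM, which offsets gains of other markers. In batch 2, where the B cell median was -0.21, the interferon median was 0.54. Markers of CD4 T cells and of other CD8 T cells were not part of this sum. The cells were gated on CD8, low CD44 and CD62L, but the purity of the sort was not measured here. Among 10 splits, too few for a share under 0.05, the labelled one was the 1 with a median this large (0.46 against 0.287 in the highest other), and an effect of the genotype on interferon signalling, in these cells or in the mouse around them, stays open and untested.

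The number of genes called set the labelled split apart from the others: 688 genes against 2 in the highest other, the labelled split being the 1 with as many, though 10 splits are too few for a share under 0.05. Among the splits that also part all 3 pairs, the fit with the block called 2742 genes for the labelled one and 0 for the other 3. Every split but the labelled one puts both genotypes on each side. The genotype difference then adds to the spread within its groups and can lower its calls, so these counts are no baseline for chance. Crossed numbers in batch 1 could mean that its libraries carry each other's genotype, but exchanging them left 0 genes called in edgeR (106 with an unadjusted p under 0.05) though 5 lists passed camera, and the log2 ratios of batch 1 correlated with those of batches 2 and 3 as labelled (r = 0.423 and 0.537). Variants linked to Nxf1 that act on neighbouring genes would place called genes near it, but 13 of 230 tested genes within 10 Mb were called, 1.03 times the share over all genes. On the whole of chromosome 19, 30 of 441 tested genes were called (6.8%), against 2.22% to 7.72% on the other autosomes. A linked variant that acts on distant genes would travel with the allele, and these counts cannot tell it apart from the allele. What stays open is any difference between the mice of a litter other than this allele.

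The number of lists called by camera did not set the labelled split apart: 8 of 10 splits gave as many, 6 in the labelled split and 9 in the highest other. The interferon list had 24 genes called in the labelled split and 0 in each other, where both genotypes lie on each side. Of the 10 splits, 4 gave as large a rho between exon number and fold change, 0.193 as labelled against 0.304 in the highest other, which sets both libraries of batch 1 with mutant replicate 2. Each of the 3 others this large also keeps both libraries of a batch on 1 side, and with batch as the block the labelled rho was -0.195. The splits that part all 3 pairs gave 0.153, 0.0861 and 0.139, and 10 splits are too few for a share under 0.05.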
